A study of Rattus norvegicus with 4 samples.

How the data were processed

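Ovaries of 4-day-old rat pups were cultured whole for 2 days on floating filters without added factor or with GDNF, per the labels' protocols, and 6 to 10 ovaries were pooled for each RNA sample, with no animal giving both of its ovaries to a group. The dose of GDNF is not given in the sources used here. There were 4 samples, 2 control and 2 GDNF, grouped by their titles. Nothing in the labels says whether replicates came from separate litters or culture days, so p-values measure only the spread between these samples, which may be partly technical. RNA was labelled with biotin and hybridised to Affymetrix rat arrays.

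The deposited values are linear array intensities (signals), computed by the authors with MAS5 per the submitters' processing notes, which give no version. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a fixed trimmed mean. In the deposited table the mean after trimming 2% at each end was 125.03 to 125.04 on every array, so a change in total RNA per ovary cannot be seen. Signals subtract a mismatch estimate, so low signals are noisy. Detection calls were not used here. The ratio of the 3' to the 5' beta-actin control probe sets was 3.76 and 3.34 in control and 2.62 and 3.61 in GDNF samples, and that of Gapdh was 1.28, 1.22, 1.11 and 1.44 in the same order. Over the probe sets tested, the log2 signals of the 2 control samples correlated at r = 0.984 and those of the 2 GDNF samples at r = 0.971. Samples of different groups were as alike. Control and GDNF replicate 1 had r = 0.983, and control and GDNF replicate 2 had r = 0.986. Control replicate 1 with GDNF replicate 2 had r = 0.976, and control replicate 2 with GDNF replicate 1 had r = 0.979. These correlations are across genes, which are not independent replicates.

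The table held 31099 probe sets. The 57 Affymetrix control probe sets were left out, which left 31042. Signals were converted to log2(signal + 1), and the 18625 probe sets whose mean was at or above the 40th percentile (a signal of about 21.4) were tested. Log2 fold changes are on this scale, GDNF minus control, which understates the change of dim genes. Probe sets were named from GEO's platform annotation: 20826 had 1 gene symbol, 436 had several and 9780 had none in that table. Entrez identifiers of 20758 of the 20826 were found in the RefSeq gene table of assembly GRCr8, used for names only, and 0 symbols changed. Of the probe sets tested, 14247 had 1 symbol, and they measured 10608 genes.

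The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. All tests were two-sided. Standard errors are limma's moderated ones, and ± gives the SD of 2 samples on the signal scale. The 24 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists held 576 genes, of which 483 had a probe set with that symbol alone and 409 were tested. Each list with at least 5 tested genes (23 lists) was tested with limma's camera, with a preset correlation between genes of 0.01, on the probe set with the highest mean for each gene, adjusted over the lists. In a further test the correlation was estimated from the samples, which leave 2 residual degrees of freedom. With it, none of the 3 lists called with the preset correlation passed.

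Named genes were, first, Gdnf, Gfra1, Ret, Ncam1, Kitlg, Amh, Gdf9, Foxl2, Fshr, Figla, Inha, Kit and Zp3. Fshr and Figla had no probe set with that symbol alone and are not analysed here. Next came the 12 genes with the smallest p in each direction among probe sets with 1 symbol, no overlap between the groups and at least a 1.5-fold difference. Last came up to 2 highest and 2 lowest members of each list. Where several probe sets measured a gene, the one with the highest mean is given, and tested probe sets of a gene that differ in direction are stated.

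The tests were run on simulated data made from the means and the variance model of the 18625 probe sets for the comparison of GDNF with control. In 50 simulations with 200 changed probe sets, limma recovered 39.8% of those changed by a log2 of 1 and 86.4% of those changed by a log2 of 2, with 6.9 false calls on average. In 50 simulations of unchanged groups, 934 probe sets on average had an unadjusted p under 0.05, and 396 (351 to 436) were also 1.5-fold apart. Camera with the preset correlation called an oocyte list shifted by 0.3 in 50 of 50 simulations and 0 of 1150 unshifted lists. With an estimated correlation it called the shifted list in 0 of 50. Simulated genes were independent, so these runs do not show how camera behaves when genes vary together.

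Alternatives were a pseudocount of 16, no filter, a filter at the 60th percentile, quantile normalization, median centring, eBayes without the trend, the replicate number as a block, 1 probe set per gene, an estimated correlation between genes, the mean of a gene's probe sets, and leaving out each sample in turn. With 1 sample left out, the lone sample of its group is assumed to vary like the other group. The replicate block leaves fewer than the 2 residual degrees of freedom of the fit without a block. Its p-values therefore rest mainly on the variance that limma models over all probe sets.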

Results

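Gene expression was measured in whole ovaries of 4-day-old rats after 2 days of organ culture, either without added factor or with glial cell line-derived neurotrophic factor (GDNF), a secreted ligand of the receptor tyrosine kinase Ret and its co-receptor Gfra1. At that age most follicles are primordial, each a small oocyte enclosed by flattened pre-granulosa cells. The title of the series gives its subject as the development of these follicles under GDNF. Each of the 4 samples was RNA from 6 to 10 pooled ovaries hybridised to 1 Affymetrix array, with 2 control and 2 GDNF samples. Median signal per array was 40 and 38.6 in control replicates 1 and 2, and 41.1 and 36.7 in GDNF replicates 1 and 2. The number of arrays limits the precision of every value below. With 2 samples against 2 the smallest two-sided p an exact permutation test can give is 0.333.

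Of the 14 oocyte genes tested, 13 had a higher mean signal in the GDNF samples, 6 of them with no overlap between the groups, and 1 a lower mean. The list shifted upward by a mean log2 fold change of 0.37 in limma's camera test (adjusted p = 1.35e-07 with the preset correlation). With the correlation between genes estimated from the samples the list did not pass (adjusted p = 0.881 with an estimated correlation). That setting also missed an oocyte shift of 0.3 in all simulations (0 of 50 called), so it cannot decide for or against the shift. Gdf9, a growth factor secreted by the oocyte, had a signal of 626 ± 114 in control and 951 ± 69.5 in GDNF ovaries (SD, n = 2 each), a log2 fold change of 0.61 (SE 0.14). Zp3, which encodes a zona pellucida glycoprotein, had 1840 ± 247 in control and 2419 ± 443 in GDNF ovaries (log2 fold change 0.39, SE 0.15, and 0.20 without GDNF replicate 2). Kit, the receptor of Kit ligand, was dimmer and overlapped between groups, at 24.5 and 47.4 in control against 80.0 and 42.3 in GDNF samples (log2 fold change 0.75, SE 0.40, and 0.29 without control replicate 1). Sycp3, a component of the meiotic synaptonemal complex, was the 1 oocyte gene with a lower mean in GDNF (log2 fold change -0.11, SE 0.17), and its direction turned without GDNF replicate 1 (0.09).

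In the fit with group as its only term, no oocyte gene passed the threshold adjusted over all probe sets tested. Adjusted over the list alone, 1 passed (Gdf9, adjusted p = 0.0379). With the replicate number as a block, Gdf9 passed over all probe sets (limma adjusted p = 0.0469), in a fit with fewer than 2 residual degrees of freedom. The control samples were far apart for this list. Relative to the mean of the 4 samples, the list mean was -0.38 and 0.02 in control replicates 1 and 2, and 0.10 and 0.27 in GDNF replicates 1 and 2. Without control replicate 1 the shift was 0.17 (adjusted p = 0.00799), and without control replicate 2 it was 0.57. The list mean also differed by 0.28 between replicate 2 and replicate 1 samples (adjusted p = 0.000807). The samples of the numbers overlapped, and that difference was below the range of 0.483 within a number. The treatment difference of 0.367 was likewise below the larger range within a group, 0.398, though the groups did not overlap. The preset test gave p-values of the size of this list's for a split that follows neither treatment nor number. With control replicate 1 and GDNF replicate 2 against the others, hypoxia genes had an adjusted p of 7.56e-09 and ribosomal protein genes 1.37e-07.

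**Figure D1:**
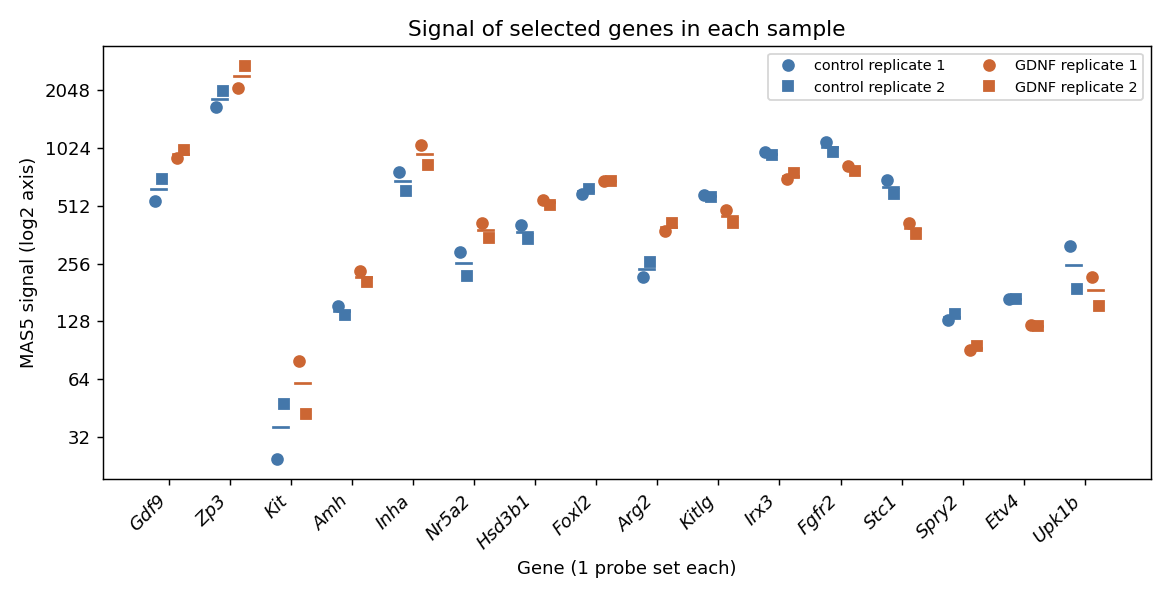
MAS5 signal (log2 axis) of 16 genes, with 1 point per sample (circles, replicate 1; squares, replicate 2; blue, control; orange, GDNF) and a bar at the mean of each group's 2 samples. Gdf9 lies at 545 and 706 in control and at 902 and 1001 in GDNF samples, while Kit overlaps between the groups. No gene shown passed the adjusted threshold over all probe sets in the fit with group as its only term.

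Granulosa cell genes went both ways. Amh, the anti-Müllerian hormone made by granulosa cells of growing follicles, had a signal of 146 ± 11.3 in control and 219 ± 20.4 in GDNF samples (log2 fold change 0.58, SE 0.14), and Inha, the inhibin alpha subunit, had 691 ± 111 and 950 ± 163 (0.46, SE 0.16). Hsd17b1, which converts estrone to estradiol, had a log2 fold change of 0.83 (SE 0.37) with overlapping groups, and 0.33 without GDNF replicate 1. Foxl2, a transcription factor of granulosa cells, had 608 ± 23.5 and 688 ± 2.90 (0.18, SE 0.10). Kitlg, the ligand of Kit, had 576 ± 9.76 in control and 453 ± 49.1 in GDNF samples (-0.35, SE 0.12). The homeobox genes Irx3 and Irx5 also had lower means in GDNF. Irx3 had 955 ± 23.5 and 731 ± 38.7 (-0.39, SE 0.10), with -0.65 in another of its probe sets. Irx5 had a log2 fold change of -0.65 (SE 0.27). With each sample left out in turn, Inha ran from 0.28 to 0.63 and Irx5 from -0.91 to -0.39.

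Of the 18 granulosa genes tested, 9 had a higher and 9 a lower mean in GDNF, and the list did not pass (mean log2 fold change 0.07, median -0.01, adjusted p = 0.573). None of its genes passed the threshold over all probe sets in the fit with group as its only term. With the replicate number as a block, a dimmer probe set of Irx3 passed (limma adjusted p = 0.0493), in a fit with fewer than 2 residual degrees of freedom. Adjusted over the list alone, 4 passed, each at an adjusted p of 0.0392: Amh, Irx3, and, outside the rule for named genes and named after their values were seen, Nr5a2 (257 ± 51.8 and 382 ± 47.5, log2 fold change 0.58) and Serpine2 (1078 ± 69.6 and 1396 ± 89.6, 0.37).

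Among theca and steroidogenic genes, Hsd3b1, which makes progesterone from pregnenolone, had a signal of 375 ± 43.1 in control and 532 ± 25.4 in GDNF samples (log2 fold change 0.51, SE 0.12). Lhcgr, the luteinizing hormone receptor, had a log2 fold change of 0.29 (SE 0.36), which became -0.14 without GDNF replicate 1. Scarb1, the receptor for high-density lipoprotein, had -0.34 (SE 0.17) and Nr5a1, a transcription factor that drives steroidogenic genes, -0.26 (SE 0.18). With each sample left out in turn, Scarb1 ran from -0.54 to -0.15 and Nr5a1 from -0.44 to -0.08. The 10 genes tested split into 5 higher and 5 lower, and the list did not pass (mean 0.01, median -0.04, adjusted p = 0.998). Hsd3b1 was the 1 gene to pass adjusted over the list alone (adjusted p = 0.0344), and none passed over all probe sets. The list mean turned to -0.02 without GDNF replicate 1. The 19 genes of cholesterol synthesis had a mean of 0.03, with 10 higher and 9 lower (adjusted p = 0.573). Mvd (0.44, SE 0.18) and Tm7sf2 (0.33, SE 0.17) were the highest of them, and Stard4 (-0.30, SE 0.24) and Lss (-0.25, SE 0.17) the lowest. Stard4 turned to 0.03 without GDNF replicate 1.

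The receptors of GDNF differed between the groups by less than their standard errors. Gfra1 had a signal of 51.8 ± 2.76 in control and 50.7 ± 6.22 in GDNF samples (log2 fold change -0.04, SE 0.21), and Ret had 48.5 ± 14.4 and 51.0 ± 16.6 (0.06, SE 0.31). Leaving out GDNF replicate 1 turned both directions, to 0.09 for Gfra1 and -0.27 for Ret. Gfra3, the co-receptor of artemin, had -0.46 (SE 0.25), Gfra2 -0.19 (SE 0.18) and the ligand Nrtn 0.17 (SE 0.23). Gdnf itself was dim in all samples, at 0.9 and 1.2 in control and 11.4 and 10.3 in GDNF samples. Gdnf and Ncam1 (20.9 and 11.1 in control, 18.5 and 7.3 in GDNF samples) lay below the signal filter and were not tested. The factor was added as protein, so its transcript does not check the treatment. The 6 genes tested in the GDNF family list had a mean of -0.08, with 2 higher and 4 lower (adjusted p = 0.599).

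Immediate early and ERK feedback genes went both ways. Spry2, a feedback inhibitor of receptor tyrosine kinases, had a signal of 136 ± 6.86 in control and 92.9 ± 3.32 in GDNF samples (log2 fold change -0.54, SE 0.15). Etv4, an ETS transcription factor, had 168 ± 0.141 and 122 ± 0.919 (-0.46, SE 0.14). Etv1 (0.24, SE 0.22) and Atf3 (0.18, SE 0.34) were the highest of the list, and both turned when 1 sample was left out, Etv1 to -0.08 without GDNF replicate 2 and Atf3 to -0.22 without control replicate 2. Of 18 immediate early and ERK feedback genes, 6 were higher and 12 lower, and the list did not pass (mean -0.09, adjusted p = 0.182). It passed without control replicate 2 (-0.17, adjusted p = 0.0413) and without GDNF replicate 1 (-0.23, adjusted p = 0.00198), and its mean turned to 0.05 without GDNF replicate 2. The list separated the replicate numbers by more than the treatments, with -0.22 between replicate 2 and replicate 1 samples, no overlap and a range of 0.151 within a number (adjusted p = 0.00171).

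Growth factors and receptors of primordial follicle development had a mean log2 fold change of 0.11 over 28 genes, 19 higher and 9 lower (adjusted p = 0.0861). Kit and Gdf9 were the highest. The list shares Kit, Gdf9 and Bmp15 with the oocyte list and Amh, Inhba, Kitlg, Amhr2 and Fst with the granulosa list. Its shift is therefore not separate from those of these lists. Fgfr2, a receptor of fibroblast growth factors, had 1033 ± 88.5 in control and 801 ± 37.7 in GDNF samples (-0.36, SE 0.11). Pdgfa had -0.48 (SE 0.22), and ran from -0.81 to -0.16 with each sample left out in turn. Gdf9 and Amh passed adjusted over the list alone (2 genes, adjusted p = 0.0467). None passed over all probe sets in the fit with group as its only term. The list passed without control replicate 1 (0.12, adjusted p = 0.0147) and without GDNF replicate 2 (0.22, adjusted p = 0.000378), and its mean was 0.01 without GDNF replicate 1. Between replicate 2 and replicate 1 samples it differed by -0.11, with overlap (adjusted p = 0.0292). Of the 19 genes of PI3K and mTOR signalling, 8 were higher and 11 lower (mean 0.03, median -0.03, adjusted p = 0.998). Foxo1 had 0.67 (SE 0.35) and Pik3r1 0.35 (SE 0.37), both with overlapping groups. Foxo1 had 0.095 without GDNF replicate 1, and Pik3r1 turned to -0.10 without control replicate 1. Foxo3, a transcription factor that restrains primordial follicle activation, had a signal of 877 ± 86.7 and 771 ± 117 (-0.19, SE 0.14). It ran from -0.34 to -0.03 with each sample left out in turn. Rptor had -0.19 (SE 0.17).

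Cell cycle genes shifted upward by a small amount, a mean log2 fold change of 0.10 over 40 genes, 31 higher and 9 lower (adjusted p = 0.000906 with the preset correlation, adjusted p = 0.881 with an estimated correlation). Ccnb1, the cyclin of mitotic and meiotic entry, had a signal of 1112 ± 144 in control and 1360 ± 152 in GDNF samples (0.29, SE 0.13), and Cenpe, a kinetochore motor, had 0.32 (SE 0.19). Tk1 (-0.13, SE 0.14) and Aurka (-0.10, SE 0.23) were the lowest, and Aurka turned to 0.23 without control replicate 2. No cell cycle gene passed over all probe sets or adjusted over the list alone. The list did not pass without control replicate 1 (0.05, adjusted p = 0.148) or without GDNF replicate 2 (0.06, adjusted p = 0.0875), and its mean was 0.15 without control replicate 2. Its means in the samples, -0.10 and 0.0029 in control and 0.01 and 0.09 in GDNF replicates 1 and 2, had the same order as those of the oocyte list. Between replicate 2 and replicate 1 samples the cell cycle mean differed by 0.088, nearly as much as between the treatments (camera adjusted p = 0.0723). The samples of the numbers overlapped, with a range of 0.116 within a number.

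Surface epithelium and mesothelium genes shifted downward, with a mean log2 fold change of -0.22 over 15 genes, 2 higher and 13 lower (adjusted p = 0.000114 with the preset correlation, adjusted p = 0.881 with an estimated correlation). The lowest were Lgals7 (-0.46, SE 0.28) and Upk1b, a uroplakin of the mesothelium (-0.41, SE 0.27). Lgals7, with a signal of 28.4 ± 0.636 in control and 20.4 ± 1.70 in GDNF samples, lay near the filter. Upk1b had overlapping groups and ran from -0.78 to -0.04 with each sample left out in turn. Brighter members of the list, named after their values were seen, were the keratin Krt7, with 482 ± 1.34 in control and 367 ± 14.4 in GDNF samples (-0.39), and the transcription factor Wt1, with 1782 ± 32.7 and 1529 ± 39.7 (-0.22). Whole ovaries were measured, so the signals of Krt7 and Wt1 cannot be assigned to the epithelium alone. The members with a higher mean were Aldh1a1 (0.21, SE 0.11) and Cdh1 (0.16, SE 0.17), and Cdh1 turned to -0.04 without GDNF replicate 1. No gene of the list passed over all probe sets or adjusted over the list alone. Without control replicate 1 the shift was -0.11 (adjusted p = 0.115) and without GDNF replicate 2 it was -0.16 (adjusted p = 0.0697), while without control replicate 2 it was -0.34. Relative to the mean of the 4 samples, the list mean was 0.22 and -0.00096 in control replicates 1 and 2. In GDNF replicates 1 and 2 it was -0.05 and -0.17. The treatment difference of -0.2231 was just below the larger range within a group, 0.2251, though the groups did not overlap. The list mean also differed by -0.17 between replicate 2 and replicate 1 samples (adjusted p = 0.00517). There the samples overlapped, with a range of 0.275 within a number.

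**Figure D2:**
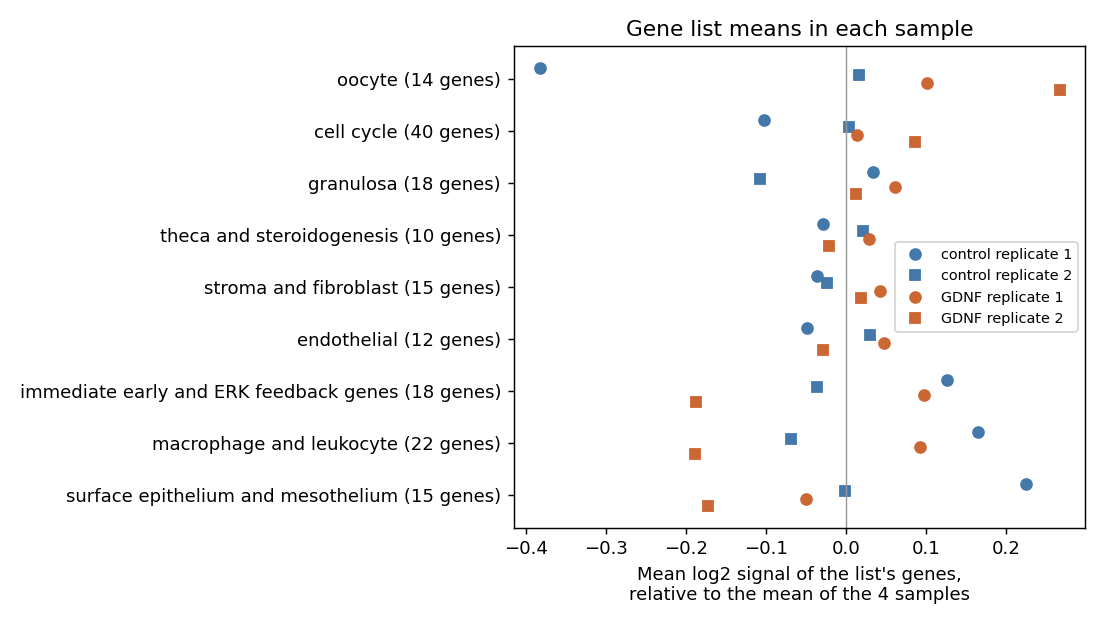
Mean log2 signal of the genes of 9 lists in each sample, relative to the mean of the 4 samples (circles, replicate 1; squares, replicate 2; blue, control; orange, GDNF). The oocyte mean runs from -0.38 in control replicate 1 to 0.27 in GDNF replicate 2, and the macrophage and leukocyte mean is above 0 in both replicate 1 samples and below 0 in both replicate 2 samples.

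Across single genes, the 12 named in each direction, with 1 symbol, no overlap and at least a 1.5-fold difference, were led by Arg2 and Stc1. Arg2, the mitochondrial arginase, had a signal of 239 ± 31.3 in control and 396 ± 25.8 in GDNF samples (log2 fold change 0.73, SE 0.14). Stc1, the secreted glycoprotein stanniocalcin 1, had 644 ± 80.0 and 392 ± 37.1 (-0.71, SE 0.13), with -0.56 (SE 0.18) in its brighter probe set. The others of the 12 on the higher side, besides Gdf9, were the junction protein Jam2 (0.69, SE 0.15), Plbd1 (0.72, SE 0.16), the matrix protein Emilin2 (0.70, SE 0.16), Armh4 (0.60, SE 0.15), Lrrn3 (0.68, SE 0.18), Ccdc61 (0.62, SE 0.18) and Ldhc, a lactate dehydrogenase of germ cells (0.69, SE 0.20). For another 3 the brightest probe set did not show the difference. Spire1 had 0.65 in the ranked probe set and 0.07 in the brightest, Smc4 had 0.76 and -0.01, and Herc3 had 1.05 and -0.19. Without 1 GDNF sample the brightest probe sets of Spire1 (-0.08 without GDNF replicate 2) and Smc4 (0.12 without GDNF replicate 1) turned.

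The others of the 12 on the lower side, besides Irx3, were the water and glycerol channel Aqp9 (-0.69, SE 0.17), the transporters Slc23a4 (-0.89, SE 0.19) and Slc25a53 (-0.79, SE 0.19), Mal2 (-0.61, SE 0.16), the phosphatase Cdc14a (-0.66, SE 0.16), Znf354b (-0.87, SE 0.22), Smg9 (-0.61, SE 0.15), the sialyltransferase St3gal1 (-0.76, and -0.47 in its brightest probe set), the interleukin receptor Il17re (-0.61, and -0.43) and Arid1b (-0.65, and -0.16 with overlapping groups). For some other named genes a dimmer probe set that was tested went the opposite way: Jam2 (-0.03), Laptm5 (0.67), Stard4 (0.14), Tk1 (0.02 and 0.39), Dnajb1 (-0.04), Etv1 (-0.01), Gfra1 (0.03), Mcam (-0.14) and Pmp22 (-0.01).

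In the fit with group as its only term, none of these genes passed the adjusted threshold. With the replicate number as a block, Stc1, Arg2, Gdf9 and Irx3 passed, though the labels do not say what the number marks. That fit leaves fewer than 2 residual degrees of freedom, so its p-values rest mainly on the variance modelled over all probe sets. With group as the only term, limma called 0 of 18625 probe sets at an adjusted p under 0.05 (smallest adjusted p = 0.999). At an unadjusted p under 0.05 there were 508, of which 198 were higher and 310 lower in GDNF. At 1.5-fold or more and unadjusted p under 0.05 there were 121, 42 higher and 79 lower. Simulated unchanged groups of independent samples gave 396 on average. Those simulations took their spread from the real samples but drew each sample independently. In the data, deviations of same-numbered samples correlated at r = 0.32 across probe sets. Such shared variation widens the spread within groups but not the difference between them. The lower count therefore does not show fewer changes than chance. With the replicate number as a block, 1355 probe sets had an unadjusted p under 0.05. With median centring of the arrays the 1.5-fold count held 76 higher and 90 lower. The count and its balance moved with single samples: 748 (177 higher, 571 lower) without GDNF replicate 1, 635 (439 higher, 196 lower) without GDNF replicate 2, 233 (99 higher, 134 lower) without control replicate 2 and 100 (65 higher, 35 lower) without control replicate 1. The groups did not overlap for 5592 probe sets, 30.0% of those tested, where chance gives 33.3%.

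The remaining lists did not pass with all 4 samples. Extracellular matrix genes had a mean of -0.03 over 37 genes, 16 higher and 21 lower (adjusted p = 0.475). Tnc, which encodes tenascin C, had a signal of 88.7 ± 1.13 in control and 64.8 ± 1.06 in GDNF samples (-0.45, SE 0.17). Eln had -0.33 (SE 0.14), Vcan 0.50 (SE 0.33) and Col15a1 0.37 (SE 0.16). With each sample left out in turn, Eln ran from -0.47 to -0.19, Vcan from 0.05 to 0.95 and Col15a1 from 0.20 to 0.54. The matrix list mean turned to 0.03 without control replicate 1, and it differed by -0.10 between replicate 2 and replicate 1 samples, with no overlap (adjusted p = 0.00869). Stroma and fibroblast genes had a mean of 0.06 over 15 genes, 10 higher and 5 lower (adjusted p = 0.331). Smooth muscle and pericyte genes had -0.14 over 10 genes, 3 higher and 7 lower (adjusted p = 0.251), with Tagln, an actin-binding protein, at 129 ± 22.9 and 82.4 ± 27.8 (-0.67, SE 0.26). Endothelial genes had 0.02 over 12 genes with a median of -0.02, 5 higher and 7 lower (adjusted p = 0.893). Sox17 (0.39, SE 0.21) and Cldn5 (0.37, SE 0.16) were the highest and Egfl7 (-0.39, SE 0.18) and Kdr (-0.19, SE 0.10) the lowest. The endothelial mean turned to -0.02 without control replicate 1. Apoptosis genes had -0.08 over 27 genes, 8 higher and 19 lower (adjusted p = 0.331), with Fas (0.30, SE 0.20) and Birc3 (0.26, SE 0.16) the highest. Casp12 and Casp1, the lowest, each had -0.48 with overlapping groups, and Casp12 had 0.0027 without GDNF replicate 2 and Casp1 -0.011 without control replicate 1.

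Macrophage and leukocyte genes had a mean of -0.10 over 22 genes, 7 higher and 15 lower (adjusted p = 0.182). C1qb (0.35, SE 0.24) and Coro1a (0.31, SE 0.32) were the highest and Laptm5 (-0.39, SE 0.35) and Cd68 (-0.32, SE 0.20) the lowest. Coro1a turned to -0.07 without control replicate 2 and Laptm5 to 0.09 without GDNF replicate 2. The list passed without control replicate 2 (-0.21, adjusted p = 0.00463) and without GDNF replicate 1 (-0.24, adjusted p = 0.0016), and its mean turned to 0.04 without GDNF replicate 2. It differed by -0.26 between replicate 2 and replicate 1 samples, with no overlap (adjusted p = 6.3e-05). Adipocyte genes had -0.32 over 5 genes with a median of -0.07, all 5 lower (adjusted p = 0.458). They passed without GDNF replicate 1 (-0.67, adjusted p = 0.0305), turned to 0.03 without GDNF replicate 2, and differed by -0.65 between replicate 2 and replicate 1 samples, with no overlap (adjusted p = 0.00443). Fabp4, a fatty acid binding protein of adipocytes, accounted for most of that mean, with 83.3 and 22.2 in control and 32.2 and 8.8 in GDNF samples. Of the erythroid list 2 genes were tested, too few for a test, and Hbb had 0.13 (SE 0.12). Oviduct epithelium genes had 0.07 over 6 genes, 4 higher and 2 lower (adjusted p = 0.573), and -0.04 without control replicate 2. Neural and glial genes had -0.01 over 7 genes, 2 higher and 5 lower (adjusted p = 0.848), and 0.03 without control replicate 2.

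Ribosomal protein genes had a mean of 0.04 over 23 genes, 21 higher and 2 lower (adjusted p = 0.12). The list passed without control replicate 1 (0.10, adjusted p = 0.000354) and its mean turned to -0.02 without control replicate 2. Oxidative phosphorylation genes had 0.02 over 35 genes, 18 higher and 17 lower (adjusted p = 0.458), and -0.02 without GDNF replicate 2. Hypoxia and glycolysis genes had -0.0052 over 19 genes with a median of 0.03, 11 higher and 8 lower (adjusted p = 0.779). They passed in opposite directions without GDNF replicate 1 (-0.15, adjusted p = 0.0145) and without GDNF replicate 2 (0.14, adjusted p = 0.000378). Heat shock and unfolded protein stress genes had -0.04 over 20 genes with a median of 0.01, 11 higher and 9 lower (adjusted p = 0.927), and 0.02 without GDNF replicate 2. Bag3, a co-chaperone, had 139 ± 2.62 in control and 106 ± 14.4 in GDNF samples (-0.39, SE 0.16), and Dnajb1 had 0.19 (SE 0.12).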

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

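All alternatives were chosen before the data were examined. In no setting without a block did limma call a probe set. With pseudocount 16 the count at 1.5-fold and unadjusted p under 0.05 was 45, with no filter 680, with the stricter filter 45 and with 1 probe set per gene 53, against 121; pseudocount and filters act on dim probe sets by construction. The labels give the samples of a number nothing in common but the number, and deviations of same-numbered samples correlated at r = 0.32 across probe sets. With the replicate block 8 probe sets passed (4 higher, 4 lower; among them Stc1, Arg2, Gdf9 and Irx3, named genes, and Car3), 224 were at 1.5-fold, and the growth factor list passed (0.113). Median centring (0.13) and the mean of a gene's probe sets (0.107) also took that list past the threshold. With an estimated correlation 0 lists passed, with the oocyte (0.367), cell cycle (0.0995) and surface epithelium (-0.223) means as they were. The estimated correlations were 0.394, 0.0612 and 0.164 against the preset 0.01. An oocyte shift simulated with independent genes was not found with an estimated correlation either. With 2 residual degrees of freedom this setting therefore cannot decide whether a list shifted. In every other setting with all 4 samples these 3 lists passed in the same direction, with oocyte means of 0.32 to 0.38. Lists near 0 turned. Hypoxia turned with pseudocount 16 (0.00087), no filter (0.045), the stricter filter (0.012), median centring (0.011) and the mean of probe sets (0.0080). Neural turned with quantile normalization (0.0018) and median centring (0.0064). Theca turned with no filter (-0.13), the stricter filter (-0.028) and the mean of probe sets (-0.00016). With no filter the GDNF family (0.20), granulosa (-0.030), apoptosis (0.0070) and oviduct (-0.087) lists turned. In the GDNF family, no filter let in Gdnf itself (2.53, from signals of 0.9 and 1.2 to 11.4 and 10.3). That near-floor gene is enough to turn a mean over 10 genes. The cause of the other turns was not tested. Of named genes, the brightest Smc4 probe set (0.0020) and Rpl22 (0.0017) turned with median centring. Gdnf, below the filter, had 0.65 with pseudocount 16 against 2.53.

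Leaving out 1 sample moved the 1.5-fold count between 100 (without control replicate 1) and 748 (without GDNF replicate 1) and the number of lists between 3 and 7 (7 without GDNF replicate 1, 5 without control replicate 2), while no probe set passed. The oocyte list passed without each sample (0.17 to 0.57). List means that changed a call or direction ran from -0.23 to 0.052 (immediate early), -0.018 to 0.033 (theca), 0.011 to 0.22 (growth factors), 0.047 to 0.15 (cell cycle), -0.086 to 0.035 (matrix), -0.24 to 0.045 (leukocyte), -0.021 to 0.058 (endothelial), -0.34 to -0.11 (surface epithelium), -0.038 to 0.17 (oviduct), -0.67 to 0.035 (adipocyte), -0.051 to 0.031 (neural), -0.094 to 0.019 (heat shock), -0.15 to 0.14 (hypoxia), -0.017 to 0.099 (ribosomal) and -0.020 to 0.059 (oxidative phosphorylation). Log2 fold changes of named genes that turned ran from -0.16 to 0.087 (Gfra1), -0.27 to 0.40 (Ret), -0.079 to 0.22 (Spire1), -0.15 to 0.12 (Smc4), -0.082 to 0.57 (Etv1), -0.22 to 0.58 (Atf3), -0.30 to 0.093 (Sycp3), -0.14 to 0.71 (Lhcgr), -0.64 to 0.030 (Stard4), -0.10 to 0.80 (Pik3r1), -0.44 to 0.23 (Aurka), -0.96 to 0.0027 (Casp12), -0.23 to 0.028 (Col1a1), -0.066 to 0.68 (Coro1a), -0.86 to 0.087 (Laptm5), -0.020 to 0.29 (Hbb), -0.041 to 0.20 (Alas2), -0.042 to 0.37 (Cdh1), -0.077 to 0.20 (Mcam), -0.74 to 0.36 (Foxj1), -0.36 to 0.11 (Cldn3), -0.74 to 0.46 (Cd36), -0.061 to 0.082 (Pmp22), -0.57 to 0.31 (Nefm), -0.88 to 0.32 (Ankrd37), -0.076 to 0.047 (Rpl22) and -0.25 to 0.085 (Ndufa5). Of 126 probe sets of named genes 28 turned, and of the 98 that kept their direction 52 moved by over 1.5 times without 1 sample. Ncam1, below the filter and untested, ran from -0.97 to 0.26. The cause of these turns was not tested. With all 4 samples, 839 of the values of named genes under these alternatives kept their direction and side of the threshold, 2 turned and 4 passed the threshold. For Gdnf and Ncam1, not tested, size was judged instead, and 1 value moved. Filters, the trend and the block leave a gene's log2 fold change as it was, and no unblocked setting called a probe set. The count therefore says little about robustness.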

Other observations

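The tests of cell shares and RNA quality below, and the counts of probe sets over other splits, were chosen after the results they bear on were seen. For the test of oocyte share, the values of Gdf9, Zp3 and Kit were known. The interferon and acute-phase lists were written after the split by replicate number was seen, without genes already seen among its top probe sets. Of their genes, 7 were still among those called in that split, so the list means are not free of it.

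The strongest structure in the data followed the replicate number and not the treatment. When the replicate 1 samples of both groups were set against the replicate 2 samples, limma called 86 probe sets, 70 higher in replicate 1 and 16 higher in replicate 2. The genes named here were chosen after their values were seen. Cxcl10, an interferon-induced chemokine, had signals of 201 and 240 in control and GDNF replicate 1 and 53.0 and 47.1 in control and GDNF replicate 2 (adjusted p = 0.000149). Mmp7, a matrix metalloproteinase of epithelia, had 174 and 377 against 33.2 and 20.9 (adjusted p = 0.000657), and Rsad2, an antiviral protein, had 298 and 286 against 123 and 130 (adjusted p = 0.00129). Lcn2, an iron-binding acute-phase protein, had 971 and 995 against 578 and 587 (adjusted p = 0.00501), and complement C3 had 1387 and 1317 against 975 and 803 (adjusted p = 0.0336). In the other direction, Fam111a had 144 and 114 in replicate 1 against 596 and 522 in replicate 2 samples (adjusted p = 7.81e-05). The meiotic cohesin genes Smc1b (147 and 166 against 248 and 297, adjusted p = 0.0288) and Stag3 (64.6 and 94.6 against 155 and 160, adjusted p = 0.0448) were also higher in replicate 2.

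The first pattern weighed was the higher signal of oocyte genes together with the lower signal of surface epithelium genes in GDNF. RNA degradation stays open, since the log2 3'/5' ratios differed by less than the range within a group (beta-actin -0.2052, range 0.465; Gapdh 0.02, range 0.375). A smaller share of surface epithelium alone would raise all other cell types alike. Granulosa, theca, stroma and endothelial genes together differed by 0.046, below the larger range within a group of 0.048, against 0.37 for oocyte genes. This goes against a smaller share of surface epithelium alone. The gap of 0.3211 was, however, within the range of 0.415 between the control samples. The gap was 0.05 in both control replicate 2 and GDNF replicate 1, so this explanation stays open with 2 samples a group. A larger share of oocytes would raise germ cell identity and oocyte growth genes alike. Growth genes (6 genes, 0.46) exceeded identity genes (6 genes, 0.24) by 0.2206, narrowly above the range within a group of 0.206. This goes against share as the whole cause, but the identity mean overlapped between the groups, with a range within a group of 0.530. A larger share of oocytes therefore stays open with 2 samples a group. Further growth of the oocytes under GDNF may contribute but was not tested.

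The next pattern was the split by replicate number. An interferon or acute-phase response in the replicate 1 samples may be part of it: the interferon list (34 genes) differed by -0.4714 and the acute-phase list (27 genes) by -0.34 between replicate 2 and replicate 1, each beyond the range within a number. Cells carried over from another tissue may be another part, since 3 of 6 lists of such cells separated the numbers beyond that range (leukocyte -0.26, adipocyte -0.65, neural 0.05), though the neural mean went against its median of -0.11 (3 genes higher and 4 lower, adjusted p = 0.822) and is no sign of neural cells; of abundant leukocyte genes, Lyz2 had 449 and 356 in replicate 1 against 359 and 347 in replicate 2 samples, Cd74 436 and 562 against 336 and 239, and of adipocyte genes Fabp4 had 83.3 and 32.2 against 22.2 and 8.8 while Acsl1 had 178 and 154 against 168 and 178. RNA degradation stays open, with log2 3'/5' ratios that differed by less than the range within a number (beta-actin 0.1477, range 0.523; Gapdh 0.15, range 0.243). A shared litter, dissection or culture day per number stays open, since the labels do not say what the numbers mark.

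The 4 samples can be split into 2 and 2 in 3 ways, too few for a share under 0.05. For probe sets past the adjusted threshold, 3 of the 3 splits gave as many as the real split (0, highest other 86), which a real count of 0 fixes by construction. For probe sets at 1.5-fold and unadjusted p under 0.05, 3 of 3 gave as many (121, highest other 841), and for lists past the threshold 2 of 3 (3, highest other 7). The split by replicate number gave the highest of each, and its 841 probe sets at 1.5-fold were several times the real 121, which points to a structure of the samples.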
